A study of Dicentrarchus labrax with 30 samples.

How the data were processed

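RNA was measured in the pituitary, the whole brain and the head kidney of European sea bass (Dicentrarchus labrax) classed as bold or shy, with 30 libraries from 10 fish. Each tissue has 5 bold and 5 shy libraries, each of 1 fish. The shy fish were 3 females and 2 males, and the bold fish were 2 females and 3 males. Per the labels, libraries were made with a stranded poly(A) mRNA kit and read as single ends of 50 nt on 3 lanes of a HiSeq instrument. The submitters' processing notes name bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.2.9, SAMtools 1.5 and featureCounts 1.6.2. The genome build, the annotation and the strand setting are not given in the sources used here. The deposited values are raw counts of reads per gene, with no normalization, for 26719 gene identifiers. Of these, 5479 carry no symbol, and the others carry 14950 distinct symbols. Of the identifiers, 0 matched the reference gene table, so the symbols are the ones in the count table, and several identifiers can share a symbol.

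Samples were tied to columns through their titles. Replicate numbers follow the order in which the samples are listed and do not pair libraries of different tissues. Total counts ranged from 3808645 to 12550808 in pituitary, from 7916478 to 20067656 in brain and from 4667992 to 26837997 in head kidney. Counting error is therefore small for genes with many reads and large for genes near 1 CPM. In 135 pairs of libraries within a tissue, 0 columns were identical.

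The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. Within each tissue, bold was compared with shy by edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr with its minimum count of 10) in R 4.3.3, with sex as a covariate. The same fit gave male minus female, and a second fit gave the interaction of behavior and sex. P values were adjusted by the Benjamini-Hochberg method over the genes tested in a tissue, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale, bold minus shy, with their standard error (SE). Levels are CPM, counts scaled to the library size with TMM factors, given as mean ± SD. Tests were two-sided.

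Tissue identity and the difference in the bold minus shy change between tissues came from 1 edgeR fit of all 30 libraries, treated as independent. A gene marked a tissue at an adjusted p under 0.05 and a log2 fold change of at least 1 against the mean of the other tissues. Whole transcriptomes were compared by a pseudo-F from squared Euclidean distances of log2 CPM (prior count 2), with an exact permutation over all 252 labelings of 5 against 5, and p values adjusted over the tissues and both factors.

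There were 36 lists of pathways, cell types and neighbouring tissues. A list was read where at least 3 members were tested, which gave 103 tests in all. Lists were tested by camera on limma 3.58.1 voom values with a preset correlation of 0.01, adjusted over lists and tissues. The same lists were also tested with an estimated correlation between genes and by fry. For each list, members were in addition adjusted over the list alone. A library's list score is the mean, over the members, of its log2 deviation from the tissue's mean. The difference in score between bold and shy fish had an exact permutation test, adjusted over the 103 tests; these score tests, and counts of genes whose groups do not overlap, were added after seeing the data.

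Genes are named by rule. Named are the genes that passed, the 5 with the smallest p in each direction, the list members that passed over all genes or over the list alone, a few genes fixed in advance for each tissue, and for the interaction genes among the 5 with the smallest p of those that passed. Other genes fixed in advance that were not tested here, such as those of further pituitary hormones, are not analysed here.

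The alternatives were size factors by median of ratios, DESeq2 1.42.0, voom with sample quality weights, no filter, a filter of at least 1 CPM in at least 5 libraries, no covariate, all 30 libraries in 1 fit, non-robust shrinkage, an adjusted p under 0.10, other distance settings, and leaving out each library in turn. Leaving out the libraries that stood apart from their tissue, and leaving out each library in the list and interaction tests, were added after seeing the data. Splits of the same libraries into groups of the same sizes were refitted, 100 within each tissue and 40 for the fits of all libraries. The fits were tested on simulated data, and what they recovered is given with the limits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sequence reads were used here.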

Results

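The series compares European sea bass at the ends of a boldness scale. Boldness was scored as the time a fish took to leave a shelter. Bold fish left early, and shy fish left very late or never. Fish were tested 4 times over 7 months, the first 3 tests were used to choose them, and 10 fish aged 478 days after fertilization were sampled. The pituitary and the brain regulate hormones and behavior, and the head kidney of fish holds both blood-forming tissue and the interrenal cells that make cortisol. Each tissue gave 5 libraries of shy fish and 5 of bold fish, and all values per group are mean ± SD with n = 5. The shallowest libraries were pituitary shy 1 with 3808645 counts, head kidney shy 1 with 4667992 and pituitary bold 4 with 5323694, and the deepest was head kidney shy 4 with 26837997. Between 18436 and 23421 genes were detected per library.

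Some libraries stood apart from the others of their tissue. Ribosomal protein genes, which encode the proteins of the ribosome, took 3.09% of counts in pituitary shy 1 and 1.92% in pituitary shy 2, both from males, and 4.11% to 5.68% in the other pituitary libraries. In brain shy 4, from a female, they took 0.0166%, against 1.71% to 2.92% in the other brain libraries. The median Spearman correlation with the other libraries of the tissue was 0.919 and 0.906 for pituitary shy 1 and 2, against 0.955 to 0.963 for the rest. It was 0.731 for brain shy 4 and 0.925 for brain shy 1. All of these libraries belong to shy fish. In head kidney, the gene with the most counts took 11.4% to 22.7% of a library.

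**Figure D1:**
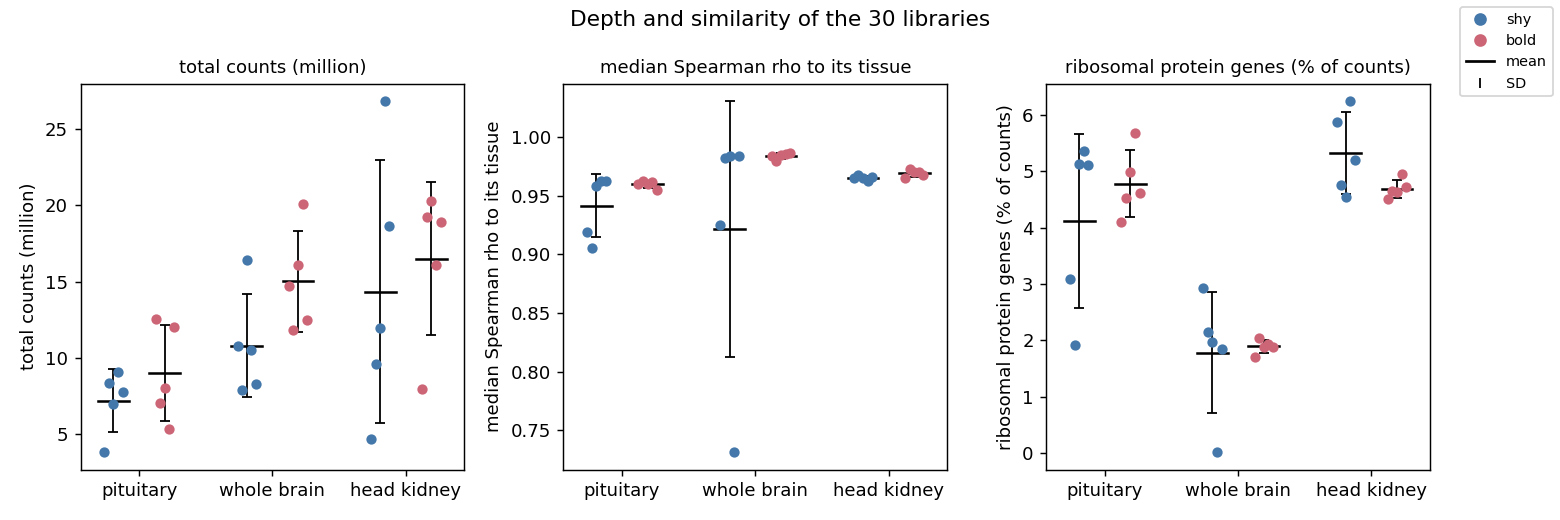
Total counts, median Spearman correlation with the other libraries of the tissue, and percent of counts in ribosomal protein genes, for each library (points), with the mean and SD of the shy and bold libraries of each tissue. Brain shy 4 has a correlation of 0.731 and 0.0166% of its counts in ribosomal protein genes.

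The tissue comparison checked the tissue labels. TSHB DLAgn_00096090, the beta subunit of thyrotropin, averaged 2435 ± 654 CPM in pituitary (SD, n = 10) and 0.0845 CPM in brain. SNAP25 DLAgn_00066930, a protein of neuronal vesicle release, averaged 1128 ± 334 CPM in brain and 0.224 CPM in head kidney. HBAA1, an alpha globin, averaged 258100 ± 70400 CPM in head kidney, and MPX, the neutrophil myeloperoxidase, 2071 ± 500 CPM. Of the neuron markers, 18 of 19 were higher in brain, and in head kidney 13 of 14 neutrophil markers and 19 of 20 erythroid markers were higher. Of 34 oligodendrocyte and myelin markers, 15 were higher and 19 lower in brain (median -1.24), and 16 were higher in head kidney: MBP DLAgn_00064210, myelin basic protein, averaged 976 CPM in brain and 54.0 CPM in head kidney, but MOG DLAgn_00174790, 1 of several identifiers with that symbol, 0.578 and 9.81 CPM. Of 20598 genes, 8601 differed between pituitary and the mean of the other tissues (5160 higher and 3441 lower), 10939 in brain (6422 and 4517) and 12376 in head kidney (4856 and 7520). Scaling by median of ratios moved the median of all genes by 0.113 in brain and by -0.112 in head kidney (log2), and 18 erythroid markers were then higher in head kidney.

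In the pituitary, most glucocorticoid-responsive, extracellular matrix and immediate early genes had higher means in bold fish. FKBP5, a co-chaperone of the glucocorticoid receptor, averaged 381 ± 186 CPM in bold and 58.9 ± 53.8 CPM in shy fish, a log2 fold change of 2.72 (SE 0.656), and each bold library lay above each shy one. It did not pass over all genes (adjusted p 0.229, and 0.00579 to 0.999 over the alternatives, the lowest by DESeq2). COL1A2, a chain of type I collagen, averaged 117 ± 33.6 CPM against 46.1 ± 15.2 CPM, a log2 fold change of 1.47 (SE 0.243), also without overlap. DUSP5, a phosphatase of MAP kinases, averaged 115 ± 60.8 CPM against 28.7 ± 11.3 CPM (2.11, SE 0.464). TSHB DLAgn_00096090 averaged 3258 ± 525 CPM against 2306 ± 610 CPM (0.57, SE 0.181), and rose adjusted over the list alone (0.0165), a list with 2 tested members.

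Of the 27 glucocorticoid-responsive genes tested, 24 had positive changes with a median of 0.53, and 7 rose when adjusted over the list alone (adjusted p 0.0235 to 0.0439), among them FKBP5, CEBPD (1.86), IRS2 (1.68) and KLF9 (0.98). The list passed camera with an adjusted p of 8.76e-05, and its score was higher in each bold library than in any shy one; the list had adjusted p = 0.818 with an estimated correlation. Of 29 immediate early genes, which neurons and other cells switch on within minutes of a stimulus, 24 were positive (median 0.80, adjusted p 7.38e-05), and 8 rose adjusted over the list alone (0.0166 to 0.0449), among them NPAS4 (2.62), DUSP5 and JUN (1.23). Of 30 extracellular matrix genes, 27 were positive (median 0.51, adjusted p 7.4e-06), and 4 rose adjusted over the list alone (0.00201 to 0.0328): COL1A1 (1.61), COL1A2, COL1A1B (2.00) and COL5A3A (1.09). The score of the immediate early list was above all shy libraries in 4 of 5 bold libraries, and that of the matrix list in 3 of 5; both had adjusted p = 0.877 with an estimated correlation. These 3 lists passed camera whichever library was left out.

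Ribosomal protein genes (45 of 58 positive, median 0.49, adjusted p 8.62e-07) and genes of oxidative phosphorylation, the respiratory chain (63 of 72, 0.44, 8.8e-07), also passed in pituitary, with 0 of 5 bold libraries above all shy ones. These lists move with pituitary shy 1 and 2, the libraries with few ribosomal protein counts: without that pair both lists passed in the opposite direction (adjusted p 7.81e-06 and 1.54e-05). Without shy 2 alone the adjusted p was 0.0505 and 0.0949. Macrophage and microglia markers (21 of 24 positive, median 0.52, adjusted p 0.0189, 2 of 5 bold libraries) did not pass without shy 2 (0.075), without bold 5 (0.0511) or without shy 1 and 2 (0.146, median 0.21). Regulators of pituitary cell identity (12 of 15, 0.74, 0.0399, 5 of 5) did not pass without sex in the model (0.076), nor without shy 1 (0.0908), shy 2 (0.095), bold 2 (0.054) or shy 1 and 2 (0.96, median 0.02). All 4 lists had adjusted p = 0.877 with an estimated correlation. Without shy 1 and 2 no shy male is left, so with sex in the model the behavior change compares 2 bold females with 3 shy females.

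Over all genes, edgeR passed 0 of 17102 pituitary genes, with 3081 at an unadjusted p under 0.05 (1826 higher and 1255 lower in bold fish) and a smallest adjusted p of 0.112. DESeq2 passed 689 (550 higher and 139 lower) and voom with quality weights passed 0. Nearly all of the genes that DESeq2 passed no longer did without shy 1 and 2. In edgeR, none of the genes with the smallest p passed. Higher in bold fish were GBP DLAgn_00238430 (1.79, SE 0.236, adjusted p 0.112) and KIAA1737 (1.63, SE 0.228, 0.112), an older symbol of the CLOCK inhibitor CIPC. Also higher were STK35 (1.68), BCAN (1.35), the matrix proteoglycan brevican, and COL1A2 (each 0.197). Each of these 5 was higher in 5 of 5 bold libraries than in any shy one. Lower in bold fish, with an adjusted p of 0.229 each, were SPRYD3 (37.7 ± 9.44 against 73.2 ± 8.60 CPM, -0.95), PDE2A (-0.60), a phosphodiesterase of cyclic nucleotides, SULT2ST1 (-0.87), MIA (-1.05) and CALL4 (-0.67). CALL4 was the only one of these 5 whose ranges overlapped. Over the lists alone, SNAP25A (0.81, neurons, 0.0401) also rose, and GMNN (-0.79, cell cycle, 0.0346), the replication inhibitor geminin, fell. Of the genes fixed in advance, the glucocorticoid receptor NR3C1 had changes of 0.11 (DLAgn_00110340) and -0.38 (DLAgn_00045010), the receptor of corticotropin-releasing hormone CRHR1 0.70, and TSHB DLAgn_00130190 0.41, and none passed.

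Whole pituitary transcriptomes separated by behavior, with a pseudo-F of 1.90 (19.2% of the variation, exact p = 0.0159, adjusted p 0.0477). Without shy 1 and 2 the pseudo-F was 1.27 (exact p = 0.143), and the exact p was also 0.05 or more without bold 1 (0.183), bold 2 (0.198), bold 3 (0.19), bold 4 (0.0714) or bold 5 (0.183). The count of genes was 73 without bold 4 and 1 without shy 2. Without shy 1 and 2 it was 0 and FKBP5 had a change of 2.11. No shy male is left in that fit, so its behavior change compares 2 bold females with 3 shy females.

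**Figure D2:**
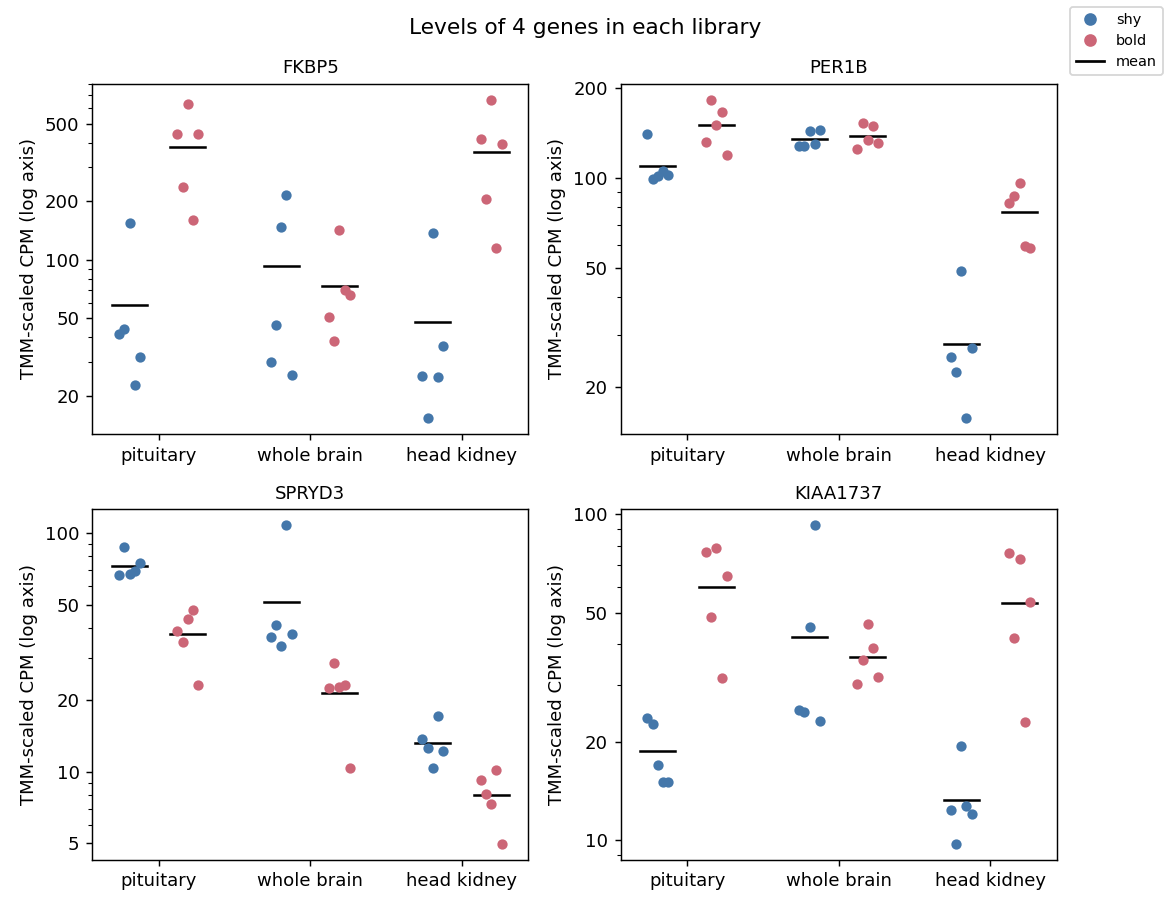
CPM on a log axis of FKBP5, PER1B, SPRYD3 and KIAA1737 in each shy (blue) and bold (red) library (points), with black lines at the group means of each tissue. FKBP5 lies between 22.8 and 154 CPM in the shy and between 159 and 628 CPM in the bold pituitary libraries.

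In the head kidney, most glucocorticoid-responsive genes had higher means in bold fish, and most ribosomal protein genes had lower ones. FKBP5 averaged 359 ± 213 CPM in bold and 47.8 ± 50.4 CPM in shy fish (3.14, SE 0.833), with overlapping ranges, and did not pass over all genes (adjusted p 0.338, and 0.00414 to 0.639 over the alternatives, the lowest by DESeq2). PER1B, a clock gene that glucocorticoids also induce, averaged 76.9 ± 17.2 CPM against 27.9 ± 12.5 CPM (1.49, SE 0.299), and each bold library lay above each shy one. TSC22D3 DLAgn_00108490, known as GILZ, averaged 153 ± 32.6 CPM against 83.8 ± 21.8 CPM (0.88, SE 0.219), also without overlap. RPL34, a protein of the large ribosomal subunit, averaged 585 ± 29.1 CPM against 737 ± 57.1 CPM (-0.33, SE 0.102), with each bold library below each shy one.

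Of 24 glucocorticoid-responsive genes, 20 were positive (median 0.64, adjusted p 9.37e-08, 5 of 5 bold libraries above all shy ones), and 11 rose adjusted over the list alone (0.00376 to 0.0404), among them FKBP5, PER1B, the kinase SGK1 (1.21) and DDIT4 (1.29), an inhibitor of mTOR signalling. Of 23 clock genes, 13 were positive (median 0.06, adjusted p 0.0382, 5 of 5), and PER1B and both copies of TEFA (1.52 and 0.74), a transcription factor of the clock's output, rose adjusted over the list alone. Ribosomal protein genes were negative in 56 of 57 (median -0.31, adjusted p 1.86e-24), and 35 fell adjusted over the list alone. Their score lay below all shy libraries in 4 of 5 bold libraries. Oxidative phosphorylation (67 of 72 negative, median -0.21, adjusted p 4.58e-14, 4 of 5 bold libraries) and the proteasome, which degrades proteins (39 of 41, -0.17, 5.55e-06, 3 of 5), were also lower. Each list that passed camera in this tissue had adjusted p = 0.877 with an estimated correlation. The glucocorticoid, ribosomal, respiratory chain and proteasome lists passed camera whichever library was left out. The clock list did not pass without shy 1 (0.0595), shy 2 (0.0902), bold 1 (0.0849), shy 4 (0.143) or bold 3 (0.0576).

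Genes of corticosteroid synthesis were negative in 8 of 9 (median -0.39, adjusted p 0.0405, 4 of 5 bold libraries below all shy ones and 1 above all of them). They did not pass without sex in the model (0.271), nor without shy 1 (0.0577), shy 2 (0.172), bold 1 (0.149), shy 3 (0.153), bold 2 (0.187), shy 4 (0.0695) or bold 3 (0.117). Their members STAR, which carries cholesterol into mitochondria (-0.24), and CYP21A2, the 21-hydroxylase (-0.53), did not pass. The ACTH receptor MC2R (-0.04), HSD11B2 (0.19), which inactivates cortisol, and the catecholamine enzymes TH (0.71), DBH (0.22) and PNMT (-0.81) did not pass either. Of the glucocorticoid receptor's copies, NR3C1 DLAgn_00110340 (0.82) rose adjusted over the list alone and DLAgn_00045010 (0.14) did not pass.

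Interferon response genes were negative in 18 of 26 (-0.17, adjusted p 0.0259, 0 of 5 bold libraries below all shy ones), and this list did not pass without shy 3 (0.163), shy 5 (0.186) or bold 4 (0.321). Muscle markers (8 of 10 negative, median -0.31, adjusted p 0.0405, 3 of 5) did not pass without sex in the model (0.117), nor without shy 1 (0.0595), shy 2 (0.151), bold 1 (0.0689), bold 2 (0.0925), shy 4 (0.0857) or bold 3 (0.0605). Liver and plasma genes (5 of 6 negative, median -1.95, adjusted p 0.0189, 1 of 5) did not pass without sex in the model (0.189), nor without shy 1 (0.236) or shy 2 (0.97).

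Over all genes, edgeR passed 1 of 15741 head kidney genes. DLAgn_00202850, which has no symbol, rose from 12.0 ± 2.05 to 35.2 ± 7.67 CPM (1.56, SE 0.185, adjusted p 0.043), higher in 5 of 5 bold libraries than in any shy one. There were 1764 genes at an unadjusted p under 0.05 (914 higher and 850 lower), and DESeq2 passed 122 (70 and 52) and voom with quality weights 0. Among the genes with the smallest p that did not pass were the amino acid transporter SLC43A2 (0.68, SE 0.0941, adjusted p 0.0772) and HLF (0.89, SE 0.131, 0.094), a transcription factor of the same family as TEFA, both higher in 5 of 5 bold libraries than in any shy one. ADAM8A (0.99) and DLAgn_00260260 (1.46) were also higher, with an adjusted p of 0.177 each. Lower were DLAgn_00265390 (-5.89, SE 0.803, 0.0772), the mitochondrial DNA-binding protein SSBP1 (-0.80, 0.177), DLAgn_00113130 (-1.55, 0.192), the betaine and GABA transporter SLC6A12 (-0.79, 0.208) and PAWR (-1.27, 0.208). DLAgn_00265390 was below all shy libraries in 5 of 5 bold libraries, with 4.92 ± 2.63 CPM in shy fish and 0.0715 ± 0.0765 CPM in bold fish.

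Whole head kidney transcriptomes separated by behavior (pseudo-F 1.498, 15.8% of the variation, exact p = 0.0159, adjusted p 0.0477), but the exact p was 0.05 or more without bold 1 (0.0714), bold 2 (0.0556) or shy 5 (0.0635). The adjusted p of DLAgn_00202850 was over 0.05 without shy 1 (0.195), shy 2 (0.12), bold 1 (0.409), bold 2 (0.0515), shy 4 (0.072), shy 5 (0.124) or bold 5 (0.065), and the count of genes was 4 without shy 3, 2 without bold 3 and 5 without bold 4.

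**Figure D3:**
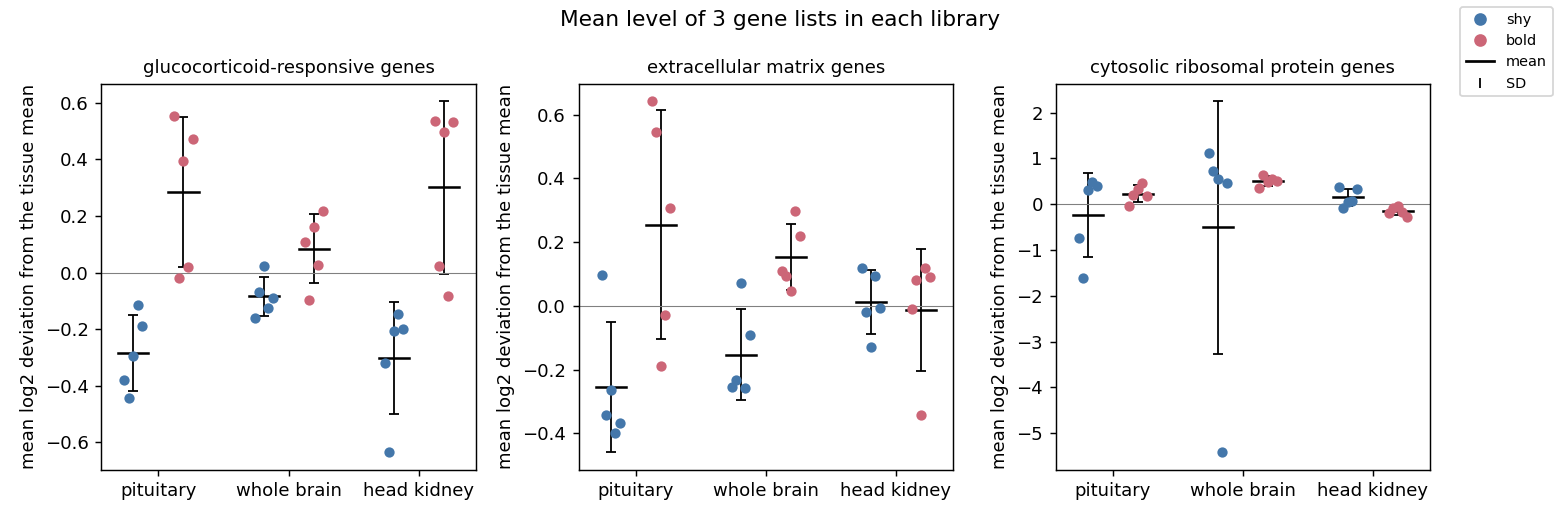
Mean log2 deviation from the tissue mean of the glucocorticoid-responsive, extracellular matrix and ribosomal protein genes in each library (points), with the mean and SD of the shy and bold libraries. All 5 bold libraries lie above all 5 shy ones for the glucocorticoid-responsive genes in pituitary and head kidney.

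In the brain, 1 gene without a symbol differed and most named genes did not. DLAgn_00265390 fell from 9.69 ± 3.00 CPM in shy fish to 0.877 ± 0.277 CPM in bold fish (-3.48, SE 0.343, adjusted p 0.0401), lower in 5 of 5 bold libraries than in any shy one. The chemokine receptor CXCR4 averaged 10.5 ± 4.63 CPM in bold and 3.45 ± 1.5 CPM in shy fish (1.73, SE 0.438), and fibronectin, FN1 DLAgn_00160200, 54.0 ± 6.46 CPM against 35.7 ± 5.75 CPM (0.63, SE 0.172, without overlap). Neither passed (adjusted p 0.888 each). FKBP5, higher in the other tissues of bold fish, had a log2 fold change of -0.00 in brain.

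Genes of GABA and glutamate synapses were positive in 47 of 53 brain genes (median 0.66, adjusted p 5.39e-08, 2 of 5 bold libraries above all shy ones). Cell cycle genes were positive in 34 of 43 (0.33, 0.00128, 3 of 5), and interferon response genes were negative in 16 of 23 (median -0.39, 0.00237, 1 of 5 below all shy ones). All 3 lists had adjusted p = 0.877 with an estimated correlation. The synapse list moves with brain shy 4 and shy 1, the libraries that stand apart: their scores were -2.53 and -0.842, against 0.242 to 0.505 in the other shy and 0.20 to 0.587 in the bold libraries. Without that pair the median was 0.13 for the synapse genes, 0.16 for the cell cycle genes and -0.20 for the interferon response genes, and the lists still passed camera (adjusted p 0.000107, 0.000629 and 0.000528). Extracellular matrix genes were positive in 25 of 32 (0.30, 0.00221, 4 of 5), with adjusted p = 0.818 with an estimated correlation. Of the members of these lists, 0 passed edgeR adjusted over the list alone, and the lists passed camera whichever library was left out.

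Immediate early genes (25 of 33 positive, median 0.50, adjusted p 0.00221, 3 of 5 bold libraries) did not pass without bold 1 (0.312) or shy 3 (0.0789). Regulators of pituitary cell identity (12 of 16, 0.33, 0.0399, 3 of 5) did not pass without sex in the model (0.0523), without any 1 of the 10 libraries (0.061 to 0.281) or without shy 1 and 4 (0.531). Both had adjusted p = 0.877 with an estimated correlation. Ribosomal protein genes (41 of 57, 0.05, 0.0116, 0 of 5) had adjusted p = 0.985 with an estimated correlation, and move with brain shy 4, which has few ribosomal protein counts. They did not pass without bold 1 (0.162) or bold 4 (0.273) and passed in the opposite direction without shy 4 (9.66e-17) and without shy 1 and 4 (2.62e-12).

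Over all genes, edgeR passed 1 of 18640 brain genes, with 254 at an unadjusted p under 0.05 (96 higher and 158 lower), and DESeq2 passed 2 and voom with quality weights 1. The other genes with the smallest p had adjusted p 0.888 each: DLAgn_00235010 (1.90), DLAgn_00205050 (0.87) and DLAgn_00221810 (1.195) were higher, and PLA2G1B (-1.93), a secreted phospholipase, PARP11 (-1.22), DLAgn_00187960 (-1.199) and ACSBG2 (-1.40) were lower. The genes fixed in advance did not pass: TPH2, the enzyme of serotonin synthesis in neurons, had -0.76, tyrosine hydroxylase TH 0.84 (DLAgn_00165950) and -0.16 (DLAgn_00209490), NPY -0.13, and NR3C1 0.47 (DLAgn_00110340) and -0.78 (DLAgn_00045010). The values of TPH2 and NR3C1 DLAgn_00045010 rest on brain shy 4, and without it they were -0.32 and -0.09. Whole brain transcriptomes did not separate by behavior (pseudo-F 1.46, exact p = 0.111, adjusted p 0.222), but did without shy 5 (2.00, exact p = 0.0159). The adjusted p of DLAgn_00265390 was 0.0155 without shy 4 and 0.0853 to 0.317 without each of the other 9 libraries, so the count of genes was 0 in those 9 fits.

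The difference between tissues in the bold minus shy change was tested in all 30 libraries, which come from 10 fish but were treated as independent. The fitted change of FKBP5 was larger than in brain by 2.76 in pituitary and by 3.26 in head kidney (log2), and the joint test had an adjusted p of 0.945. For PER1B the head kidney exceeded the brain by 1.52 (adjusted p 0.202, joint 0.489). Of 20598 genes, edgeR passed 0 in the joint test, with 819 at an unadjusted p under 0.05. The tests of pairs of tissues also passed 0, with 890 for pituitary and brain, 734 for head kidney and brain, and 1149 for pituitary and head kidney at an unadjusted p under 0.05. Without the 4 libraries that stood apart, 2 genes passed the joint test and 2 that of head kidney and brain. No other tool was run for this comparison, so a change that passed in 1 tissue alone is not shown to differ from the other tissues.

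Males and females were compared in the same fits. In edgeR, 0 genes passed in pituitary, brain and head kidney, with 2316, 89 and 564 at an unadjusted p under 0.05, and DESeq2 passed 0, 1 and 7. With 1 library left out, edgeR passed 1 gene in pituitary without bold 1 and 1 gene in head kidney without bold 4. The pseudo-F of sex was 1.34 (exact p = 0.397), 0.684 (exact p = 1) and 0.843 (exact p = 0.825).

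Whether the bold minus shy change differed between the sexes was tested as an interaction. In pituitary, some housekeeping genes were low in the shy males alone: RPL19-A, a ribosomal protein, averaged 59.7 CPM in the 2 shy males, 1083 CPM in shy females, 986 CPM in bold females and 980 CPM in bold males (interaction 4.18, adjusted p 3.87e-05). CCT3 (4.01, adjusted p 3.91e-05), a subunit of the chaperonin that folds actin and tubulin, and COX7B (4.71), of the respiratory chain, and PSA3 (3.04), with 5.62e-05 each, also had their lowest mean in the shy males. Of the lists, 39 of 72 respiratory chain genes, 26 of 58 ribosomal protein genes, 6 of 15 pituitary regulators, 3 of 11 catecholamine genes, 1 of 27 glucocorticoid-responsive genes and 0 of 30 extracellular matrix genes had a positive interaction. In all, edgeR passed 1639 pituitary genes (1275 positive and 364 negative). Both shy males are pituitary shy 1 and 2, which stand apart, so the interaction could not be fitted without them, and with 1 library left out the count was 711 without shy 2, 900 without bold 1, 986 without shy 4 and 1051 without shy 5.

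In head kidney 3 genes had a negative interaction (adjusted p 0.0482 each). APOC1, an apolipoprotein (-7.66), averaged 11.0 CPM in the 2 shy males, and DLAgn_00082150 had -5.96 and DLAgn_00005730 -8.79. The count was 0 without shy 1, shy 2, shy 4, bold 3, bold 4 or bold 5, 1 without shy 5, 9 without bold 1 and 17 without bold 2. In brain edgeR passed 0, with 76 at an unadjusted p under 0.05, and DESeq2 passed 1.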

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

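All tests of explanations in this part were chosen after the result was seen, except the test of a sex-dependent effect in all 3 tissues and the splits of the samples, which were planned.

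Most glucocorticoid-responsive genes had higher means in bold fish in pituitary (24 of 27 with positive changes) and head kidney (20 of 24), led by FKBP5, and pituitary shy 3 (154 CPM, next 44.3, gap over range 0.836) and head kidney shy 3 (137 CPM, next 36.2, 0.829) stood out among the shy libraries for FKBP5. The tables argue against transcript loss in pituitary shy 1 and 2 as the whole cause. Without them the list's median was 0.49 (0.535 with them) and its adjusted p by camera 2.51e-05, in fits that compare 2 bold females with 3 shy females. With 1 library left out the adjusted p was 6.19e-06 to 0.0125. Among the blood cell lists in head kidney the highest median was 0.038 (B cells), while the glucocorticoid list's was 0.636. The upper quartiles of the other blood cell lists, 0.0938 to 0.174, argue against a larger share of those cells in bold fish. Single macrophage markers went both ways, adjusted over the list alone: PTPRC, the common leukocyte antigen (0.49), and CD209 (0.77) rose, and APOEB (-0.73) fell. For B cells the upper quartile was 0.543 (11 of 17 positive, adjusted p 0.0994 by camera), so a larger share of B cells stays open. More interrenal tissue in bold head kidney is not excluded. Corticosteroid synthesis genes had a median of -0.389, but the difference in their score was -0.278 (exact p = 0.381 by permutation). That score was below all shy libraries in 4 bold libraries and above all of them in 1. Time of day or order of sampling stays open and cannot be told apart from behavior, since no label gives a time; the clock list in head kidney (adjusted p 0.0382, 13 of 23 positive) does not decide, as it was lost with an estimated correlation (adjusted p = 0.877) and without shy 1, shy 2, shy 4, bold 1 or bold 3 (0.0576 to 0.143). No biological explanation, such as a difference in cortisol between bold and shy fish, was tested, and the list had adjusted p = 0.818 in pituitary and adjusted p = 0.877 in head kidney with an estimated correlation.

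In pituitary 1639 genes passed the interaction of behavior and sex, led by RPL19-A (3.87e-05), CCT3 (3.91e-05), and COX7B and PSA3 (5.62e-05 each), and an interaction test marks them because the change differs between the sexes. A candidate explanation is transcript loss in both shy male libraries, which resemble brain shy 4, a library of a female: there the genes with a positive interaction had a median deviation of -3.92 (log2), against -0.00569 for other genes and 1.16 for those with a negative interaction. Of the positive ones 93.2% were lower in brain shy 4, against 50.1% of the others. For the genes with a positive interaction, an effect of behavior that differs between the sexes in all 3 tissues is argued against. Their median interaction was 0.0768 in head kidney (interquartile range 0.428) and 2.06 in pituitary. In brain it was -0.389, in libraries that include shy 4. These genes were chosen by their pituitary interaction, which raises the 2.06, and other genes are not covered. A sex-dependent effect in pituitary alone stays open, untested, because the shy males are the 2 libraries in question.

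DLAgn_00265390 passed in brain alone (-3.48, adjusted p 0.0401), and its change was -5.89 in head kidney (0.0772) and -3.58 in pituitary (SE 0.811, 0.229), where 4 of 5 bold libraries lay below all shy ones. Raw counts were 54 to 176 in shy and 9 to 24 in bold brain libraries, 19 to 103 and 0 to 4 in head kidney, and 12 to 131 and 1 to 12 in pituitary. Head kidney bold 3 stood out among the bold libraries (0.202 CPM, next 0.0565, gap over range 0.72). Reads shared with a near-identical copy, or a variant against the reference that differs between the fish, stay open and cannot be told apart from a change in level. A variant would lose reads to the same degree in every tissue. The joint test of a difference between tissues had an unadjusted p of 0.0788 but treats libraries of the same 10 fish as independent. It cannot decide on a near-identical copy, since the share of reads lost to a copy can differ between tissues. The sequence of the reads was not used here. A regulated difference between bold and shy fish stays open too and was not tested.

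Chance alone marks about 1 in 20 groups for a library far from its group; 256 groups of gene levels and 48 of library measures were examined, 15.2 would be marked by chance and 23 were. In pituitary, STK35 in shy 4 (10.4 CPM, next 17.6) had a gap over range of 0.855, PER1B in shy 1 (140 CPM, next 106) 0.853, and COL1A1 in shy 2 (12.9 CPM, next 43.3) 0.733. The share of the top 10 genes in pituitary bold 2 (20.8%, next 17.9%) had 0.791. In brain shy 4, NR3C1 DLAgn_00045010 (536 CPM, next 99.1) had 0.981 and TPH2 (13.3 CPM, next 4.61) 0.91. The same library had 19165 genes detected (next 22129, 0.739), a TMM factor of 0.728 (next 1.01, 0.885) and a median Spearman correlation of 0.731 (next 0.925, 0.765). In head kidney bold 5, CYP21A2 (203 CPM, next 73.8) had 0.883, MC2R (33.6 CPM, next 9.40) 0.92 and STAR (448 CPM, next 172) 0.83. These genes of steroid synthesis were high in that library, in which RPL15 (0.811), RPL29 (0.746) and RPL22 DLAgn_00096830 (0.798) were low. Other gaps in head kidney were MC2R in shy 1 (0.741), SSBP1 in bold 4 (0.715), TSC22D3 DLAgn_00108510 in shy 1 (0.785), RPL34 in bold 3 (0.73) and TEFA DLAgn_00187840 in shy 3 (0.816). In head kidney 3 genes passed the interaction of behavior and sex: APOC1, DLAgn_00082150 and DLAgn_00005730 (adjusted p 0.0482 each).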

How the results depend on the processing

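Tests without the libraries that stood apart, and list and interaction tests without 1 library, were chosen after the result was seen. The others were planned. Without pituitary shy 1 and 2 no shy male is left, so pituitary fits with sex then compare 2 bold females with 3 shy females. Of the called lists' values under the alternatives, 211 kept direction and side of the threshold, 97 no longer passed and 5 reversed. For the named genes these were 2357, 44 and 25, and 81 newly passed. Most named genes did not pass before any alternative, so most of the 2357 are values that stayed on the side of not passing. The 44 concern only the few genes that had passed, and are not to be read as a share of all values. Where a value changed, the cause was not tested.

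With DESeq2 the count of behavior genes was 689 in pituitary, 2 in brain and 122 in head kidney. Sex genes by DESeq2 were 1 in brain and 7 in head kidney, and interaction genes 1 in brain and 21 in head kidney. Behavior genes were 2 without a filter in pituitary, 4, 0 and 16 (pituitary, brain, head kidney) with all 30 libraries in 1 fit, and in head kidney 0 with voom and quality weights, 4 without sex, 0 without robust shrinkage and 4 at an adjusted p under 0.10. Without the libraries that stood apart, DESeq2 passed 3 pituitary and 6 brain genes, and the tissue interaction passed 2 genes jointly and 2 between head kidney and brain.

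With 1 library left out, behavior genes ranged from 0 to 73 in pituitary, 0 to 1 in brain and 0 to 5 in head kidney; sex genes from 0 to 1 in pituitary and 0 to 1 in head kidney; and interaction genes from 711 to 2242 in pituitary and 0 to 17 in head kidney. The pseudo-F ranged from 1.38 to 2.23 in pituitary, 1.13 to 2.00 in brain and 1.29 to 1.61 in head kidney. It was 1.27 in pituitary without shy 1 and 2, and 1.37 in head kidney on the most variable genes.

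The lists that passed were 0 in pituitary, 0 in brain and 0 in head kidney with an estimated correlation, and 0, 0 and 0 by fry, against 7, 7 and 9 by camera with the preset correlation. With 1 library left out the count ranged from 3 to 9 in pituitary and 5 to 11 in head kidney. Without shy 1 and 2, oxidative phosphorylation (adjusted p 1.54e-05) and ribosomal protein genes (7.81e-06) reversed in pituitary. The call of pituitary regulators was lost (0.96): their rank against other genes reversed, and their median went from 0.74 to 0.02. Ribosomal protein genes reversed in brain without shy 1 and 4 (2.62e-12) and ranged from 9.66e-17 to 0.273 with 1 library left out.

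Some named genes, none of which passed over all genes, reversed. TSHB DLAgn_00130190 in pituitary was -0.14 without shy 1 and 2 (-0.13 by DESeq2). TH DLAgn_00209490 in brain was 0.23 with voom and quality weights, 0.021 without sex, 0.095 without shy 1 and 4, 0.10 by DESeq2 without them, and -0.48 to 0.35 with 1 library left out. MC2R in head kidney was 0.22 without sex, 0.014 with all 30 libraries in 1 fit and -0.49 to 0.10 with 1 left out. DBH in head kidney was -0.043 with voom and quality weights and -0.45 to 0.60 with 1 left out. The ranges with 1 left out were -0.32 to 0.27 for NR3C1 DLAgn_00110340 in pituitary, -1.01 to 0.40 for NPY in brain and -0.12 to 1.23 for TH DLAgn_00165950 in head kidney.

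No paired analysis was run, because no label ties libraries of different tissues to a fish. The samples are listed in the same order of behavior and sex in each tissue, which alone does not show which libraries share a fish. Libraries of different tissues come from the same 10 fish, so the tests between tissues treat as independent what is not. A pattern shared by tissues, such as that of the glucocorticoid-responsive genes, is likewise not made of independent observations. The number of libraries, their depth and the spread between them limit what could be seen. The coefficient of variation between libraries, estimated by edgeR over all genes, was 0.297 in pituitary, 0.471 in brain and 0.243 in head kidney. Data were simulated gene by gene with the spread of the real libraries, so genes varied independently. There edgeR recovered 45, 0 and 58 of 100 genes changed 2-fold in pituitary, brain and head kidney. Of 100 genes changed 4-fold it recovered 84, 47 and 92. For the interaction of behavior and sex it recovered 30, 0 and 55 of those changed 4-fold.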

Other observations

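The tests of list scores, the counts of genes whose groups do not overlap and the grouping of the splits by the libraries that stand apart were chosen after the result was seen, and the splits of the samples were planned.

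SPRYD3 was the 1 gene of 13789 tested in all 3 tissues whose bold libraries lay below the shy ones in each: 37.7 against 73.2 CPM in pituitary, 21.5 ± 6.67 against 51.6 ± 31.7 CPM in brain (-1.16) and 7.95 ± 1.97 against 13.2 ± 2.51 CPM in head kidney (-0.70). For 0 genes the bold libraries lay above in all 3. In pituitary and head kidney both, 10 genes lay above and 2 below. The tissues come from the same 10 fish, so separation in several of them is not independent. No chance share was computed for these counts. KIAA1737 averaged 53.6 ± 22.1 CPM in bold and 13.3 ± 3.66 CPM in shy head kidney (2.03), as it was higher in bold pituitary. In all, 2.14% of pituitary genes, 1.01% of brain genes and 3.01% of head kidney genes had groups that did not overlap, where chance gives 0.794%.

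Other genes of the head kidney passed adjusted over the list alone. The common leukocyte antigen PTPRC (0.49) and the lectin CD209 (0.77) rose, and apolipoprotein APOEB (-0.73) fell, among macrophage markers. The thyroid hormone receptor THRB (0.90), the prolactin receptor PRLR (0.98) and the leptin receptor LEPR (0.67) rose. Elastin ELNA (1.101) and the melatonin enzyme ASMT (0.94) rose, and the interferon-induced ligase TRIM25 (-0.79) and the peptide-processing enzyme CPE (-0.94) fell.

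The score of the glucocorticoid-responsive list was higher in bold fish by 0.568 in pituitary and 0.602 in head kidney, with an exact p of 0.00794, the smallest that 5 against 5 can give, and an adjusted p of 0.164 each. The same held for catecholamine genes (0.626) and pituitary regulators (0.501) in pituitary and clock genes (0.234) in head kidney. Each of these lists was higher in 5 of 5 bold libraries and none passed after adjustment (0.164 each). The difference for pituitary regulators moves with pituitary shy 1 and 2, whose scores were -0.844 and -0.798. The other shy libraries had 0.108 to 0.152 and the bold ones 0.206 to 0.305. In brain the score of the glucocorticoid-responsive list was also higher in bold fish, by 0.167 (exact p = 0.0476, adjusted p 0.337). There 4 of 5 bold libraries lay above all shy ones.

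Splits of the same libraries show how far chance can be excluded. For the genes that passed in head kidney, as many were seen in 13 of 100 splits (1, highest other 18), so chance is not excluded, and the split with 18 points to a structure of the samples. In brain it was 4 of 100 (1, highest other 157), which alone would make chance less likely, but a split that passed 157 genes points to a structure of the samples. Where 0 genes passed, every split has as many, so the splits do not bear on chance there: 100 of 100 for behavior in pituitary (0, highest other 3), 100 of 100 for sex in pituitary, brain and head kidney (0 each, highest other 80, 1 and 3), and 40 of 40 for the behavior change between tissues (0, highest other 286). The splits with 80 and 286 again point to a structure of the samples. For genes at an unadjusted p under 0.05, the real head kidney grouping had the highest count (1 of 100 splits, 1764, highest other 1698). The next split came close and this was 1 of several such checks, so chance is less likely there but not excluded. In pituitary it was 4 of 100 (3081, highest other 3153), which alone would make chance less likely. However, the 3 other splits with as many were among the 39 that keep shy 1 and 2 in 1 group, and 0 were among the 60 that part them. The pituitary count is therefore not told apart from the structure that these libraries give. Chance is not excluded in brain (36 of 100, 254, highest other 5403). As many lists passed camera in 58, 34 and 30 of 100 splits of pituitary (7, highest other 13), brain (7, highest other 13) and head kidney (9, highest other 15), so chance is not excluded for the number of lists. For tissue identity chance is excluded, with 1 of 40 splits for pituitary (8601, highest other 867), brain (10939, highest other 5979) and head kidney (12376, highest other 2527).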
